A study of Mus musculus with 120 samples.

How the data were processed

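RNA was measured by sequencing in 18 libraries of dissected mouse embryos and 10 libraries of E14 mouse embryonic stem cells, part of a series of 120 samples. The other samples of the series are genomic libraries and were not analysed here. Per the labels' protocols, embryo RNA was extracted with guanidine thiocyanate and made into libraries with Nextera XT, a kit that inserts adapters by transposition, and cell RNA was extracted with Trizol and made into libraries with a NEBNext RNA kit. The values are whole-number counts per gene, as the authors deposited them, in 1 table for each material. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.9, BWA and the genome build mm10, without saying which step each was used for. The counting tool, the annotation and the use of strand are not given in the sources used here, so overlapping and antisense genes and near-identical gene copies may share counts.

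Each table held 23154 genes. The cell table held 27 names turned into dates, which were left as they stood, and no gene lacked a name. Columns were matched to samples by their names, and 6 columns of the embryo table that matched no sample were not used. Gene positions came from a RefSeq table of GRCm38.p6, the same assembly as mm10, and all 237 genes eligible to be named had a position, 5 of them by a synonym. Totals per library ran from 5.15 to 17.1 M counts in embryos (median 11.1) and from 5.96 to 13.2 M in cells (median 8.75). The ribosomal transcript Rn45s took 0.1515 to 6.907% of embryo counts and up to 0.4787% of cell counts. TMM factors ran from 0.659 to 1.371 in embryos and 0.8868 to 1.159 in cells. Replicates were compared by a chi-square of their counts over genes: per degree of freedom it lay between 40.4 and 135 in the 9 embryo pairs and between 3.78 and 63.9 in the 8 cell pairs, so no library counted as a copy of another.

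Genes passing edgeR's filterByExpr (minimum count 10, minimum total 15) were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit, TMM scaling, Benjamini-Hochberg adjusted p under 0.05). All groups of a table entered 1 fit without a replicate block, and 17 contrasts were drawn from the fits, 12 in embryos and 5 in cells. The standard error of a log2 fold change is its size over the square root of the F statistic. Where a side had no counts, the fold is a lower bound from a floor of 3 counts over that group, and where it had 1 to 3 counts levels are given without a fold. SDs are over libraries, and floors cover counting error only. Library pairs and trios are small, so tests pool the spread over all groups of the table.

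Gene lists, 30 in all with 24 used in embryos and 23 in cells, were fixed with the contrasts, the tests, the named-gene rule and the alternatives before the data were examined. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the lists of a contrast, for lists with at least 3 tested members. Members called were counted over all genes and again with p adjusted over the list alone. For each contrast, the genes eligible to be named were the 5 largest rises and 5 largest falls among genes that passed, had an average log2 CPM of at least 3 and showed no overlap between the replicates of the sides. From each list described, the 4 called members with the smallest p, the 2 with the smallest p in the minority direction and up to 2 that did not pass, in list order, were eligible as well. Results of some eligible genes are not reported here. Genes called between A and P at E7.5, up to 200 per direction, were tested as sets in the cell line. Median fold changes per chromosome were set against 10000 random lists matched on expression for the shifted chromosomes.

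The edgeR gene test, camera with the preset correlation and the chromosome medians were tested on simulated counts, with 200 changed genes for the gene test. The same counts also held a list of 20 genes raised by a log2 fold change of 1 and chromosome 19 genes raised 1.5-fold. Scaling and adjustment thus acted on more true changes than the 200. Genes were drawn independently of each other. Fry, camera with an estimated correlation, DESeq2, the overlaps, the splits and the sets from the embryo were not simulated. At changes of 2-fold, 4-fold and 8-fold, edgeR recovered 1.49%, 37.3% and 66.7% of them for E6.5 ExE minus Epi among 14403 genes, and 40.3%, 76.1% and 90.9% for D8 KO minus WT among 14629. For E7.0 P minus A it recovered 1.49%, 29.9% and 56.1%, and for the difference of P minus A between stages 0%, 5.97% and 37.9%. No simulated gene was called in the wrong direction. Unchanged genes called numbered 5, 16, 4 and 2 for these 4 contrasts in the order given. Alternatives were DESeq2 1.42.0, DESeq2's size factors or total counts in edgeR, a filter of 20 counts in 2 libraries, no filter, a fit of the compared groups alone, a replicate block and leaving out each replicate. Chosen after the data were seen were a replicate block within stage, library sizes without Rn45s, and the cell fit without genes of chromosomes 6, 11, 14 and Y. Python 3.11.15 with matplotlib 3.10.9 drew the figures.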

Results

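RNA counts were analysed for 28 libraries in 2 tables. In the first, 18 libraries came from mouse embryos of the ICR strain, an outbred stock, from 6.5 days post coitum (E6.5) over 7.0 days (E7.0) to 7.5 days (E7.5). At these stages the epiblast, the source of the embryo proper, forms the germ layers. Embryos had been dissected into an extra-embryonic part (ExE) and an embryonic part. At E6.5 the embryonic part is named Epi, at E7.0 it was split into regions named A and P, and at E7.5 into A, P and AM. Each of these 9 groups had 2 libraries. Total counts per embryo library ran from 5.15 to 17.1 M (mega). In the second table, 10 libraries came from E14, a mouse embryonic stem cell line, unedited (WT) or with the enhancer named Enh9E deleted by CRISPR-Cas9 (KO). Cells were taken undifferentiated (D0) or after 8 days of neural differentiation (D8), with 3 KO and 2 WT libraries per day, and totals of 5.96 to 13.2 M. The labels used here give neither the position nor the target gene of Enh9E, so the deletion was not checked against a target. Nothing in the labels says whether replicates came from separate embryos or cultures, so p-values measure the spread between these samples, which may be partly technical. At E6.5 and E7.5 Y-linked transcripts were present in one replicate and nearly absent from the other, so there the replicates held different embryos. All KO libraries share a chromosome shift described below, so KO minus WT p-values do not separate the deletion from other differences of the line. Levels are in CPM, counts per M counts after TMM scaling, fold changes are on the log2 scale with their standard error, and gene positions refer to GRCm38.

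The first question was how the extra-embryonic part differs from the embryonic part at each stage. At E6.5, genes of the extra-embryonic ectoderm, the tissue that gives rise to the placenta, rose in ExE over Epi, and epiblast genes fell. Of 19 extra-embryonic ectoderm genes, 17 rose (19 when adjusted over the list alone), with a median log2 fold change of 4.20 (camera, adjusted p = 2.19e-32, and adjusted p = 4.42e-05 with an estimated correlation). Elf5, a trophoblast transcription factor on chromosome 2 (103412098 to 103450989), stood at 50.9 ± 24.4 CPM in ExE and 0.511 ± 0.399 in Epi (SD, n = 2). Its log2 fold change was 6.58 ± 0.83. Wnt7b, a Wnt ligand, rose by 7.73 ± 0.78 (adjusted p = 2.08e-05), and Esrrb, a nuclear receptor of trophoblast and naive stem cells, by 6.13 ± 0.66. Cdx2 and Hand1 did not pass, at 3.30 ± 1.02 and 4.38 ± 1.47. Among 14 epiblast genes, 9 fell, also when adjusted over the list alone (median -3.40, adjusted p = 6.97e-11, and adjusted p = 0.0282 with an estimated correlation). Otx2, a homeobox gene on chromosome 14 (48656781 to 48667644), fell by 6.79 ± 0.80 on the log2 scale, and Nodal, a signal of the TGF-beta family, fell by 5.61 ± 0.92. Sox2 did not pass, at 0.88 ± 0.60.

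Other lists at E6.5 moved in both directions. Of 12 naive pluripotency genes, 5 rose and 2 fell (7 and 3 when adjusted over the list alone, adjusted p = 0.000841, and adjusted p = 0.0255 with an estimated correlation). Nr0b1, Zfp42 and Klf5 rose by 4.55 ± 0.58, 3.61 ± 0.56 and 4.21 ± 0.67. Nanog fell by 2.56 ± 0.51, and Fgf4, which had no count in ExE, was at least 67.3-fold lower there. Of 9 genes of the anterior visceral endoderm, a signalling tissue that patterns the epiblast, 5 fell (6 when adjusted over the list alone, adjusted p = 0.0243 with an estimated correlation). Cer1, a secreted antagonist of Nodal and Wnt signals, fell by 7.78 ± 1.56. Of 18 primitive streak genes, 5 fell (6 when adjusted over the list alone), among them Fgf8 by 6.19 ± 1.06 and Mixl1 by 5.02 ± 1.2. That list passed with the preset correlation (adjusted p = 0.000714) and not otherwise (adjusted p = 0.289 with an estimated correlation). Of 19 visceral endoderm genes, which mark the outer layer around both parts, 2 rose (3 when adjusted over the list alone, adjusted p = 0.0477, and adjusted p = 0.718 with an estimated correlation). These were Gata6 (1.98 ± 0.58) and Cited1 (2.51 ± 0.72). Imprinted genes split, with 4 of 19 higher and 5 lower (6 and 5 when adjusted over the list alone, adjusted p = 0.743). Igf2 rose by 3.65 ± 0.53 and Mest fell by 3.02 ± 0.53. Fgf15 stood at 73.3 ± 10.8 CPM in Epi and had 1 count in ExE.

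In all, 531 genes were higher and 755 lower in ExE at E6.5, of 14403 tested with edgeR. Scaling by total counts alone turned the split from 41.3% to 63.2% higher and shifted the median of all genes by 0.33. Each library mattered to the count: it was 386 or 603 without Epi replicate 1 or 2, and 355 or 547 without ExE replicate 1 or 2.

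At E7.0, ExE was compared with the mean of A and P. All 19 extra-embryonic ectoderm genes rose, also when adjusted over the list alone, by a median of 4.92 (adjusted p = 2.21e-40, and adjusted p = 6.53e-05 with an estimated correlation). Tfap2c, a transcription factor of trophoblast, rose by 8.13 ± 0.60 and Ddah1, an enzyme that breaks down methylated arginines, by 3.51 ± 0.28 (adjusted p = 8.44e-07). Elf5 reached 52.6 ± 36.4 CPM in ExE against 1 count each in A and P. Of 12 naive pluripotency genes, 8 rose, also when adjusted over the list alone, where 1 fell as well (median 2.88, adjusted p = 5.83e-08, and adjusted p = 0.00273 with an estimated correlation). Esrrb rose by 6.84 ± 0.53, Nr0b1 by 5.41 ± 0.46 and Zfp42 by 4.22 ± 0.43. Nanog did not pass, at -1.24 ± 0.44. Among 14 epiblast genes, 9 fell and Dppa4 rose by 3.65 ± 0.76, with the same counts when adjusted over the list alone (adjusted p = 4.02e-06, and adjusted p = 0.0798 with an estimated correlation). Fgf5, a growth factor of the primed epiblast, fell by 5.93 ± 0.90.

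Of 9 targets of BMP signalling, 5 rose at E7.0, also when adjusted over the list alone (adjusted p = 0.000449, and adjusted p = 0.205 with an estimated correlation). Id2, an inhibitor of basic helix-loop-helix factors, rose by 3.56 ± 0.40, Smad6 by 3.59 ± 0.65 and Smad7 by 2.10 ± 0.45. Id3 did not pass, at -0.38 ± 0.37. Of 19 visceral endoderm genes, Cited1 and Ihh rose, by 2.86 ± 0.57 and 3.22 ± 0.69, and these 2 also passed when adjusted over the list alone (adjusted p = 0.0024, and adjusted p = 0.533 with an estimated correlation). In total 1442 genes were higher and 1173 lower. Total-count scaling gave 69.7% higher against 55.1%, with a shift of the median of 0.17. The count was 1245 without ExE replicate 2, which held 5.15 M counts, 4555 without ExE replicate 1 and 1624 without P replicate 1.

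At E7.5, blood and vessel genes joined the extra-embryonic ectoderm genes in ExE, compared with the mean of A, AM and P. Of 12 haemato-endothelial genes, 9 rose (10 when adjusted over the list alone), with a median of 3.57 (adjusted p = 6.52e-10, and adjusted p = 0.00238 with an estimated correlation). Gata1, the erythroid transcription factor, rose by 3.47 ± 0.34 and Runx1, a regulator of blood cell formation, by 3.68 ± 0.53. Hbb-bh1, an embryonic beta-globin on chromosome 7 (103841638 to 103843162), stood at 35.0 ± 38.7 CPM in ExE and 0.195 ± 0.0904 in P, with no count in A or AM. Its adjusted p was 0.000136. Of 19 extra-embryonic ectoderm genes, 14 rose, also when adjusted over the list alone (median 4.35, adjusted p = 0.000599 with an estimated correlation). Wnt7b rose by 7.59 ± 0.54, Esrrb by 6.41 ± 0.46 and Ddah1 by 2.93 ± 0.24, while Cdx2 stood at 0.07 ± 0.71. Of 12 Hox genes, which mark posterior identity, 5 rose, also when adjusted over the list alone (median 2.27, adjusted p = 0.0277, and adjusted p = 0.192 with an estimated correlation). Hoxd8 rose by 4.82 ± 1.07 and Hoxa7 by 4.37 ± 1.29.

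Visceral endoderm genes were also higher in E7.5 ExE: 10 of 19 rose, also when adjusted over the list alone (adjusted p = 4.77e-08, and adjusted p = 0.295 with an estimated correlation). Cited1 rose by 3.87 ± 0.51, Fgb, a fibrinogen chain, by 3.50 ± 0.64 and Rbp4, a retinol carrier, by 4.21 ± 0.86. The A side was uneven for this list, with median levels of -0.46 and 4.61 log2 CPM in its replicates against 8.37 and 9.20 in ExE. Naive pluripotency genes rose in 7 of 12 cases and fell in 1, with the same counts when adjusted over the list alone (adjusted p = 2.56e-08, and adjusted p = 0.00238 with an estimated correlation). Of 17 neural ectoderm genes, 4 fell and Pou3f1 rose by 2.56 ± 0.52, with the same counts when adjusted over the list alone (adjusted p = 0.0327 with an estimated correlation). Nodal had no count in ExE and was at least 45.1-fold lower there than the mean of the embryonic regions. Altogether 1934 genes were higher and 1139 lower. Total-count scaling put 44.5% higher against 62.9%, with a shift of the median of -0.30. The count fell to 661 without ExE replicate 2 and to 2000 without ExE replicate 1.

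**Figure D1:**
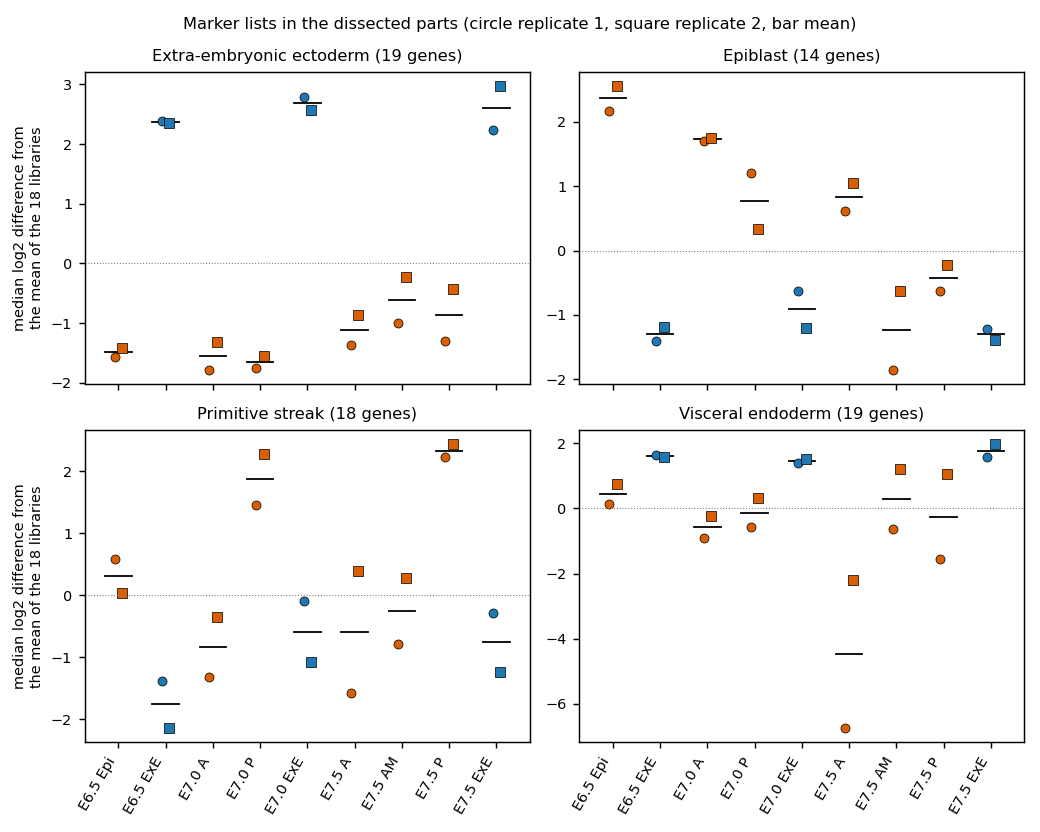
Median log2 difference of 4 marker lists in each embryo library from the mean of the 18 libraries (vertical axis), by stage and part (horizontal axis). Points are libraries, bars are means of 2, blue marks ExE and orange the embryonic parts. All ExE libraries lie at 2.23 or above for the extra-embryonic ectoderm list, and E7.5 A replicate 1 lies at -6.75 for the visceral endoderm list.

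The ExE calls of the stages, made on separate libraries, overlapped. Of the 19 extra-embryonic ectoderm genes, 14 rose at every stage, among them Elf5, Wnt7b, Esrrb, Tfap2c and Ddah1. In total 363 genes were higher in ExE at all 3 stages, where independent lists of these sizes would share 7.14, and 348 were lower at all of them, against 4.86. The stages share 1 fit, with the same filter and the same estimate of spread for each gene. Some overlap beyond independent lists can come from this alone, so 7.14 and 4.86 do not serve as a test. In the main fit 5 genes were called in opposite directions at different stages, against 4 with total counts, 20 with DESeq2 and 39 without a filter. Fold changes at E6.5 and E7.0 correlated across genes with Pearson's r = 0.63 and Spearman's rho = 0.66. For E7.0 and E7.5 these were 0.59 and 0.61, and genes are not independent replicates. Leaving out single libraries gave fewer shared higher genes: 78, 148, 131 and 197 without E6.5 Epi replicate 1, Epi replicate 2, ExE replicate 1 and ExE replicate 2, and 239 without E7.5 ExE replicate 2. Shared lower genes numbered 193, 145 and 190 without E6.5 Epi replicate 1, ExE replicate 1 and ExE replicate 2, and 100 without E7.5 ExE replicate 2.

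The next question was how the regions of the embryonic part differ. At E7.0, primitive streak genes as a list were higher in P than in A. None of the 18 passed over all genes, while 12 did when adjusted over the list alone, and 17 of 18 had a positive fold change. The median was 2.58 (adjusted p = 6.89e-23, and adjusted p = 0.0171 with an estimated correlation). T, the Brachyury transcription factor of the streak, stood at 4.44 ± 1.10 and Mixl1 at 3.89 ± 1.11 without passing. The mesenchymal list (4 of 8 when adjusted over the list alone, adjusted p = 0.0304 with an estimated correlation) and the Wnt target list (4 of 14, adjusted p = 0.0289) were higher in P as sets, with no member past the threshold over all genes. So was the immediate early list, of genes such as Fos and Jun that respond quickly to stimuli, with a median of 1.41 and no member passing even when adjusted over the list alone (adjusted p = 0.0171 with an estimated correlation). The neural ectoderm list was lower in P, with a median of -0.81 and no member passing either way (adjusted p = 0.0289 with an estimated correlation). The primitive streak list shares T, Sp5 and Cdx1 with the Wnt target list and Snai1 with the mesenchymal list. The rises of these lists are therefore not independent.

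A single gene passed at E7.0, and it lies outside the naming rule, so it is named after its value was seen: Grrp1, a gene for a glycine- and arginine-rich protein, was higher in P by 4.32 ± 0.62 (adjusted p = 0.0283). At an unadjusted p under 0.05, 492 genes passed, and DESeq2 called 14. Total-count scaling shifted the median of all genes by 0.14. The Grrp1 call was lost without any 1 of the 4 libraries.

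At E7.5, primitive streak and Hox genes were higher and neural ectoderm and epiblast genes lower in P than in A. Msgn1, a regulator of presomitic mesoderm on chromosome 12 (11208382 to 11208948), had no count in A and 19.8 ± 19.4 CPM in P, at least 208-fold higher (adjusted p = 0.0389). Tbx6, a T-box factor of the same tissue, rose by 5.44 ± 1.02. They are the 2 of 18 streak genes that passed (9 when adjusted over the list alone, adjusted p = 0.0208 with an estimated correlation). Hox genes passed as a list with none over all genes and 5 of 12 when adjusted over the list alone. Their median was 2.86 with members at 0 set to their bound (adjusted p = 0.0115 with an estimated correlation). Otx2 fell by 4.79 ± 0.72, alone of 17 neural ectoderm genes (7 when adjusted over the list alone, adjusted p = 0.00178 with an estimated correlation). Otx2 and Utf1 (-3.65 ± 0.70) fell of 14 epiblast genes (7 when adjusted over the list alone, adjusted p = 0.0417 with an estimated correlation). The neural ectoderm and epiblast lists share Otx2, Sox2 and Pou3f1, so they are not independent. Alx1, a homeobox gene of head mesenchyme, fell by 6.50 ± 0.91 and Nr0b1 fell by 4.54 ± 0.69.

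Among the largest rises in E7.5 P under the naming rule, which asks for an average log2 CPM of at least 3, were Fgg, Slco4c1 and Mageb16. Fgg, the fibrinogen gamma chain, rose by 5.88 ± 0.80, Slco4c1, an organic anion transporter, by 4.69 ± 0.62, and Mageb16 by 4.48 ± 0.48. Of 19 visceral endoderm genes none passed over all genes and 8 did when adjusted over the list alone, with a median of 3.44 (adjusted p = 3.34e-17, and adjusted p = 0.121 with an estimated correlation). Apoa1, an apolipoprotein, stood at 3.84 ± 1.97 without passing. The replicates of A differed for this list, at median levels of -0.46 and 4.61 log2 CPM, and those of P stood at 5.83 and 8.07. Counts were 29 higher and 5 lower genes. With total counts alone 5 were higher and 5 lower, and the median of all genes shifted by -0.45. No gene was called by edgeR without A replicate 1, 76 were without A replicate 2 and 10 without P replicate 2.

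In AM, endoderm genes were higher than in A at E7.5 and epiblast genes were lower. Of 15 definitive endoderm and axial mesoderm genes, 4 rose (8 when adjusted over the list alone), with a median of 2.95 (adjusted p = 2.41e-10, and adjusted p = 0.0351 with an estimated correlation). They were Cpn1, a carboxypeptidase subunit (4.10 ± 0.57), the pioneer factors Foxa2 (2.95 ± 0.56) and Foxa1 (4.44 ± 0.98), and Krt19, a keratin (3.78 ± 0.70). Sox17 did not pass, at 4.10 ± 1.14. Of 14 epiblast genes, 5 fell (8 when adjusted over the list alone, adjusted p = 0.0351 with an estimated correlation). Dnmt3b and Dnmt3a, the de novo DNA methyltransferases, fell by 2.66 ± 0.47 and 1.78 ± 0.32, and Utf1 by 4.20 ± 0.71. Of 17 neural ectoderm genes, Pou3f1 fell by 4.47 ± 0.82 and Sox2 by 3.78 ± 0.70 (5 passed when adjusted over the list alone, adjusted p = 0.00958 with an estimated correlation). Pou3f1, Sox2 and Otx2 are in the epiblast list too, so the falls of these lists are not independent. Nr0b1 had no count in AM and 4.91 ± 0.294 CPM in A, at least 47.7-fold lower in AM.

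Visceral endoderm genes were higher in AM as well. Fgb rose by 5.26 ± 1.07, Dab2, an endocytic adaptor, by 3.65 ± 0.79 and Cited1 by 3.22 ± 0.75, which makes 3 of 19 (10 when adjusted over the list alone, adjusted p = 3.25e-18, and adjusted p = 0.108 with an estimated correlation). AM stood at median levels of 6.44 and 8.29 log2 CPM for this list, against -0.46 and 4.61 in A. Fgg rose by 6.64 ± 0.81 and Slco4c1 by 5.89 ± 0.64. The totals were 166 higher and 60 lower genes. The count fell to 36 without A replicate 1, 118 without AM replicate 1 and 89 without AM replicate 2, and to 3 in a fit of these groups alone.

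Between AM and P, anterior genes were higher in AM. Alx1 rose by 7.07 ± 0.93, Otx2 by 4.20 ± 0.70 and Dkk1, a secreted Wnt antagonist on chromosome 19 (30545876 to 30549496), by 2.72 ± 0.44. Dkk1 was the member of the anterior visceral endoderm list that passed, of 9 (6 when adjusted over the list alone), and the median was 2.41 with members at 0 set to their bound (adjusted p = 0.00191 with an estimated correlation). Otx2 was the member of the definitive endoderm list that passed, of 15 (4 when adjusted over the list alone, adjusted p = 0.026 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, fell by 2.84 ± 0.43. Of 18 primitive streak genes, Nkx1-2 fell (8 when adjusted over the list alone, adjusted p = 0.026 with an estimated correlation), with 2 counts in AM and 55.1 ± 52.9 CPM in P. Hox genes were lower as a list, with 2 of 12 passing when adjusted over the list alone and none over all genes (adjusted p = 0.0192 with an estimated correlation).

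Counts between AM and P were 6 higher and 10 lower genes. Total-count scaling gave 10 higher and 1 lower, with a shift of the median of 0.44. No gene was called by edgeR without AM replicate 1 or P replicate 1, 2 were without AM replicate 2 and 10 without P replicate 2.

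The P minus A difference itself was compared between stages. Fgg, Slco4c1, Mageb16 and Amot, a regulator of the Hippo pathway, had a larger P minus A difference at E7.5 than at E7.0, by 6.13 ± 0.98, 4.94 ± 0.79, 4.72 ± 0.61 and 3.37 ± 0.50. They are the 4 genes that passed. The visceral endoderm list moved the same way, with a median of 2.92, no member passing over all genes or when adjusted over the list alone, and an adjusted p of 1.18e-10 (adjusted p = 0.612 with an estimated correlation). Fold changes at the stages correlated across genes at r = 0.11 and rho = 0.08. With 1 gene called at E7.0, the overlap of 0 between the edgeR calls of the stages carries no information. At an unadjusted p under 0.05 there were 492 and 1080 genes, and DESeq2 shared 5 higher genes and no lower one. No interaction gene was called without E7.0 P replicate 1 or E7.5 A replicate 1, 18 were without E7.5 A replicate 2, and 1 was without E7.0 A replicate 1, E7.0 A replicate 2, E7.0 P replicate 2 or E7.5 P replicate 2. Total-count scaling also gave none, with a shift of the median of -0.59.

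Time within each part was the third question. Every E7.0 library held the Y-linked transcript Ddx3y, while replicate 2 of each E6.5 and E7.5 group had at most 1 count of it. Contrasts of E7.0 with another stage therefore mix stage with the sex of the embryos. From E6.5 Epi to the mean of A and P at E7.0, mesenchymal genes stood higher and naive pluripotency genes lower as lists. Of 8 mesenchymal genes, none passed over all genes and 3 did when adjusted over the list alone, with a median of 0.97 (adjusted p = 0.00395, and adjusted p = 0.509 with an estimated correlation). Cdh2, N-cadherin, stood at 1.40 ± 0.50. None of 12 naive genes passed either way, with a median of -0.41 (adjusted p = 0.0324, and adjusted p = 0.332 with an estimated correlation). Nanog stood at -0.23 ± 0.41. The edgeR test called 0 genes, with 1237 at an unadjusted p under 0.05, and DESeq2 called 43. The shift of the median under total counts was 0.16. The edgeR count was 1 without E6.5 Epi replicate 1 or E7.0 A replicate 2.

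In A, anterior visceral endoderm genes fell from E7.0 to E7.5. Dkk1 fell by 2.50 ± 0.43, the member that passed of 9 (7 when adjusted over the list alone), and the list median was -2.48 (adjusted p = 1.71e-08, and adjusted p = 0.0177 with an estimated correlation). Hhex did not pass, at -2.21 ± 0.56. Alx1 rose by 5.23 ± 0.84, Meis1, a homeobox cofactor, by 3.88 ± 0.68 and Fgfr2 by 3.37 ± 0.60. Among the largest falls under the naming rule were Fgg (-6.67 ± 0.81), Pga5 (-6.37 ± 1.11) and Srgn (-5.89 ± 0.71). None of 19 visceral endoderm genes passed over all genes and 3 did when adjusted over the list alone, with a median of -2.46 (adjusted p = 9.71e-11, and adjusted p = 0.299 with an estimated correlation). Median levels of that list were 6.02 and 6.56 log2 CPM in E7.0 A against -0.46 and 4.61 in E7.5 A. The mesenchymal list had a median of 1.45, with none of 8 passing over all genes and 3 when adjusted over the list alone (adjusted p = 0.000873, and adjusted p = 0.299 with an estimated correlation). Counts were 26 higher and 59 lower. Total-count scaling called 161 genes, 72.0% of them higher against 30.6%, with a shift of the median of 0.43. The count was 14 without E7.5 A replicate 1, 25 without E7.0 A replicate 1 and 163 without E7.0 A replicate 2.

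In P, genes of the anterior visceral endoderm and epiblast lists fell and Hox genes rose from E7.0 to E7.5. Otx2 fell by 5.19 ± 0.73, Eomes, a T-box factor of the early streak, by 4.41 ± 0.66 and Lhx1 by 3.81 ± 0.65. Gsc had no count at E7.5 and was at least 78.8-fold lower than at E7.0. Lhx1 and Gsc are 2 of 9 in the anterior visceral endoderm list (4 when adjusted over the list alone, adjusted p = 0.00102 with an estimated correlation). Lhx1 is in the primitive streak list too and Gsc in the definitive endoderm and axial mesoderm list, so their fall does not identify the tissue. Otx2 was the member that fell of 14 epiblast genes (8 when adjusted over the list alone, adjusted p = 0.017 with an estimated correlation). Cdkn1a rose by 2.96 ± 0.44. Hox genes were higher as a list: none of 12 passed over all genes and 6 did when adjusted over the list alone, with a median of 3.02 with members at 0 set to their bound (adjusted p = 0.0015 with an estimated correlation). Of 9 retinoic acid genes, none passed over all genes, and 5 higher and 1 lower passed when adjusted over the list alone (adjusted p = 0.0453 with an estimated correlation). Aldh1a2, the enzyme that makes retinoic acid, stood at 9.15 ± 1.84 and Cyp26a1, which degrades it, at -3.90 ± 0.84. In all 4 genes were higher and 7 lower, with a shift of the median of -0.17 under total counts and 3 higher and 9 lower once Rn45s was left out of the library sizes. No gene was called by edgeR without E7.5 P replicate 1, and 1 was without E7.0 P replicate 1.

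In ExE, haemato-endothelial and Hox genes rose from E6.5 to E7.5. Hbb-bh1 and Tal1, a regulator of blood and vessel progenitors, had no count at E6.5 and were at least 212-fold and 142-fold higher at E7.5, and Lmo2, a partner of Tal1, rose by 5.26 ± 1.12. These are 3 of 12 haemato-endothelial genes (7 when adjusted over the list alone, adjusted p = 0.00571 with an estimated correlation). Hoxb2 and Hoxd1 rose from no count to at least 37.9-fold and 31.0-fold, which makes 2 of 12 Hox genes (6 when adjusted over the list alone, adjusted p = 0.0123 with an estimated correlation). Of 8 mesenchymal genes, Vim, Cdh11 and Cdh2 rose, by 5.77 ± 0.82, 5.13 ± 0.84 and 3.71 ± 0.69 (5 when adjusted over the list alone, adjusted p = 1.51e-06, and adjusted p = 0.202 with an estimated correlation). Of 19 imprinted genes, Ndn, Mest and Sgce rose, by 2.64 ± 0.50, 2.53 ± 0.52 and 1.64 ± 0.37 (4 higher and 1 lower when adjusted over the list alone, adjusted p = 0.0102, and adjusted p = 0.202 with an estimated correlation). In total 134 genes were higher and 6 lower, and total-count scaling called 66, with a shift of the median of -0.26. The count was 16 and 22 without E6.5 ExE replicate 1 and 2, and 78 without E7.5 ExE replicate 1.

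In the cell line, the first question was what neural differentiation did in unedited cells. From D0 to D8, naive pluripotency genes fell and neuronal genes rose. Of 14 naive genes, 13 fell, also when adjusted over the list alone (median -5.56, adjusted p = 2.91e-12, and adjusted p = 0.0994 with an estimated correlation). Tbx3, a factor of the naive network, fell by 7.37 ± 0.30 and Tfcp2l1 fell by 7.90 ± 0.55. Dppa3 did not pass, at -0.72 ± 0.69. Of 19 neurogenesis genes, 18 rose, also when adjusted over the list alone (median 5.40, adjusted p = 4.57e-13, and adjusted p = 0.0994 with an estimated correlation). Dll1, a Notch ligand, rose by 9.02 ± 0.44 and Map2, a dendritic microtubule protein, by 7.54 ± 0.39. Of 23 neural ectoderm genes, 15 rose and 2 fell (18 and 2 when adjusted over the list alone, adjusted p = 5.98e-07, and adjusted p = 0.142 with an estimated correlation). Pax6 rose by 6.72 ± 0.47 and Zic1 by 7.79 ± 0.46, while Sox2 fell by 0.86 ± 0.23.

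Genes of brain regions also rose in WT. Of 17 forebrain and midbrain genes, 11 rose (13 when adjusted over the list alone), with a median of 3.17 with members at 0 set to their bound (adjusted p = 0.00569, and adjusted p = 0.142 with an estimated correlation). Otx1 rose by 5.52 ± 0.82 and Six3 by 6.64 ± 1.10. Of 11 ventral neural tube genes, 7 rose (8 when adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.727 with an estimated correlation). Foxa2 rose by 4.70 ± 0.69, and Olig2, a motor neuron and oligodendrocyte factor with no count at D0, by at least 156-fold. Of 19 imprinted genes, 8 rose and 3 fell, with the same counts when adjusted over the list alone (adjusted p = 0.00569, and adjusted p = 0.0994 with an estimated correlation). Nnat rose by 8.33 ± 0.51, Cdkn1c by 5.99 ± 0.38, and Phlda2 fell by 4.70 ± 0.74. Ptn, a secreted growth factor, had no count at D0 and was at least 625-fold higher at D8. Hes5, a Notch effector, was at least 555-fold higher. In all 4080 genes were higher and 4288 lower of 14629 tested. Total-count scaling gave 62.5% higher against 48.8%, with a shift of the median of 0.30.

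In KO cells, too, naive pluripotency genes fell and neuronal genes rose from D0 to D8. Of 14 naive genes, 13 fell, also when adjusted over the list alone (adjusted p = 1.13e-11, and adjusted p = 0.0944 with an estimated correlation), with Tbx3 at -5.68 ± 0.22. Of 19 neurogenesis genes, 16 rose and Stmn2 fell by 1.04 ± 0.34, with the same counts when adjusted over the list alone (adjusted p = 1.34e-08, and adjusted p = 0.181 with an estimated correlation). Dll1 rose by 7.99 ± 0.35 and Map2 by 5.97 ± 0.32. Of 23 neural ectoderm genes, 18 rose and 3 fell (19 and 3 when adjusted over the list alone, adjusted p = 1.12e-07, and adjusted p = 0.128 with an estimated correlation), with Pax6 at 7.85 ± 0.41. Of 17 forebrain and midbrain genes, 14 rose and En2 fell by 1.89 ± 0.42 (15 and 1 when adjusted over the list alone, adjusted p = 0.00384, and adjusted p = 0.149 with an estimated correlation). Of 14 visceral endoderm genes, 10 rose and 3 fell, with the same counts when adjusted over the list alone (adjusted p = 0.0478, and adjusted p = 0.181 with an estimated correlation). Gata4, an endoderm transcription factor on chromosome 14 (63198914 to 63271712), rose by 3.21 ± 0.26 and Trf, transferrin, fell by 4.75 ± 0.40. Of 8 mesenchymal genes, 6 rose and Fn1, fibronectin, fell by 3.48 ± 0.28, with the same counts when adjusted over the list alone (adjusted p = 3.28e-06, and adjusted p = 0.0944 with an estimated correlation). Gkn2, a secreted protein known from the stomach, had no count at D0 and was at least 1440-fold higher at D8. In total 4880 genes were higher and 4550 lower. Fold changes in WT and KO correlated across genes at r = 0.87 and rho = 0.83.

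At D0 the question was how undifferentiated KO cells differ from WT. Transcripts of the Y chromosome were nearly absent from KO libraries. Ddx3y stood at 0.167 ± 0.0634 CPM in KO (n = 3) and 48.0 ± 2.83 in WT (n = 2), a log2 fold change of -7.97 ± 0.33 (adjusted p = 6.93e-07). Eif2s3y had 1 count in KO and 35.3 ± 3.28 CPM in WT, and Uty fell by 5.07 ± 0.35, so that all 3 tested members of the Y-linked list fell, also when adjusted over the list alone (adjusted p = 0.000142 with an estimated correlation). Of all 4 tested genes of the Y chromosome, 3 were called lower. Nfatc4, a calcium-responsive transcription factor on chromosome 14, rose by 2.08 ± 0.32 and Naglu, a lysosomal enzyme on chromosome 11, by 1.82 ± 0.26, while Vim fell by 1.65 ± 0.26. Pluripotency lists gave no call: none of 14 naive genes passed over all genes or when adjusted over the list alone (adjusted p = 0.854), and of 14 epiblast genes none passed over all genes and 1 fell when adjusted over the list alone (adjusted p = 0.276). Nanog stood at 0.44 ± 0.72 and Sox2 at -0.23 ± 0.21. In all 27 genes were higher and 13 lower. The fit pools the spread over both days, and D8 replicates differed more from each other than D0 replicates did. A low count here thus does not show that the lines barely differ. The count was 15, 4 and 3 without KO replicate 1, 2 and 3 and 4 without either WT replicate, 25 under total counts and 2033 in a fit of these groups alone.

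At D8, neuronal genes were lower and endoderm and epithelial genes higher in KO than in WT. Of 19 neurogenesis genes, 15 fell (16 when adjusted over the list alone), with a median of -1.80 (adjusted p = 1.21e-13, and adjusted p = 0.0656 with an estimated correlation). Dcx, a microtubule protein of young neurons on chromosome X (143855842 to 143933396), stood at 15.9 ± 5.05 CPM in KO and 96.6 ± 28.1 in WT and fell by 2.60 ± 0.32. Map2 fell by 1.97 ± 0.23 and Neurog2, a proneural factor, fell by 2.33 ± 0.36. Of 14 visceral endoderm genes, 8 rose, also when adjusted over the list alone (median 1.95, adjusted p = 5.23e-06, and adjusted p = 0.0214 with an estimated correlation). The list members Apoa1, Apoa2, Apoa4, Afp, Fgb and Serpina1a had too few counts to be tested. A parietal endoderm list, described further below, rose as well, so the kind of endoderm is not settled. Gata4 rose by 2.84 ± 0.29 (163 ± 57.5 against 22.8 ± 5.24 CPM), Gata6 by 2.89 ± 0.43 and Dab2 by 2.23 ± 0.36. Of 9 epithelial genes, 5 rose, also when adjusted over the list alone (adjusted p = 0.0031, and adjusted p = 0.0656 with an estimated correlation). Krt8 and Krt18, keratins of simple epithelia, rose by 2.94 ± 0.50 and 2.11 ± 0.43, and Epcam by 1.19 ± 0.21.

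Neural progenitor lists did not pass as sets at D8. Of 23 neural ectoderm genes, 3 fell, also when adjusted over the list alone: Ncam1 by 1.67 ± 0.22, Nes by 1.39 ± 0.20 and Hes5 by 1.37 ± 0.31 (adjusted p = 0.251). Sox2 stood at -0.22 ± 0.21. Of 17 forebrain and midbrain genes, En2 fell by 1.74 ± 0.46, also when adjusted over the list alone (adjusted p = 0.755). Gkn2 and Gkn1, secreted proteins known from the stomach, rose by 4.55 ± 0.72 and 4.58 ± 0.80. All 3 tested members of the Y-linked list fell, also when adjusted over the list alone (adjusted p = 0.00358 with an estimated correlation), and Eif2s3y had no count in KO, at least 525-fold lower. Of all 4 tested genes of the Y chromosome, 3 were called lower. In total 1834 genes were higher and 1205 lower, 60.3% higher. The higher share was 48.1% with DESeq2's size factors, 37.7% with total counts, where the median shifted by -0.20, and 49.0% once Rn45s was left out of the library sizes. It was 48.5% with the filter of 20 counts in 2 libraries, 49.7% with DESeq2, 52.7% without a filter and 59.2% with a replicate block. Rn45s took at most 0.0885% of counts in any D8 library, so the 49.0% cannot be put down to its amount. The split between higher and lower genes thus depends on scaling and filter. The count was 777 and 1277 without WT replicate 1 and 2, 5463 without KO replicate 1, 1762 without KO replicate 3, and 705 in a fit of these groups alone.

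**Figure D2:**
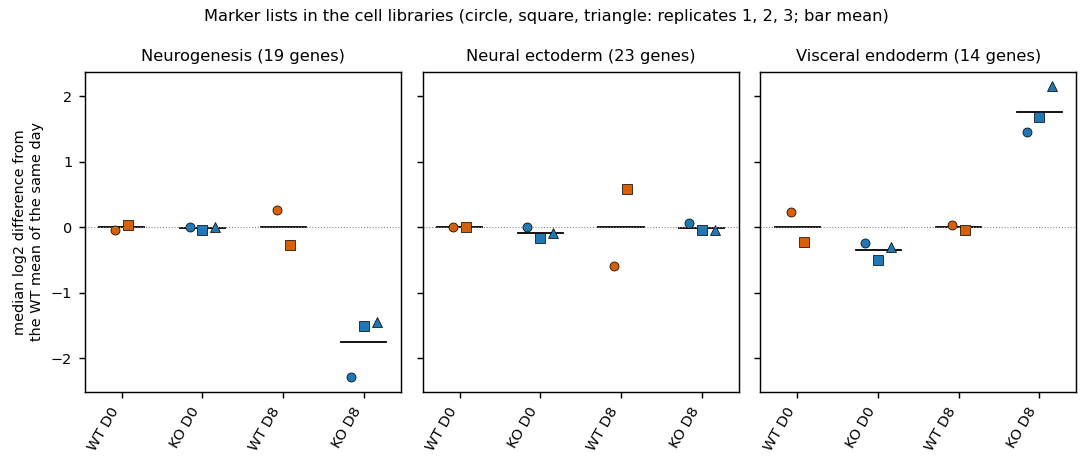
Median log2 difference of 3 marker lists in each cell library from the WT mean of the same day (vertical axis), by genotype and day (horizontal axis). Points are libraries, bars are group means, blue marks KO and orange WT. The KO D8 libraries lie between -2.29 and -1.44 for neurogenesis and between 1.45 and 2.15 for visceral endoderm, while WT D8 libraries lie at -0.59 and 0.59 for neural ectoderm.

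The KO minus WT difference was then compared between days. Visceral endoderm genes differed more at D8 than at D0: 3 of 14 passed (7 when adjusted over the list alone), with a median difference of 2.12 (adjusted p = 2.02e-05, and adjusted p = 0.0451 with an estimated correlation). Gata4, Cited1 and Dab2 had differences of 2.11 ± 0.40, 2.58 ± 0.55 and 2.22 ± 0.50. Of 19 neurogenesis genes, Dll3 and Elavl3 passed, at -2.64 ± 0.50 and -2.63 ± 0.50, and these 2 also passed when adjusted over the list alone (median -1.68, adjusted p = 0.000676, and adjusted p = 0.639 with an estimated correlation). Of 8 mesenchymal genes, Snai1 and Pdgfra passed, at 2.92 ± 0.46 and 2.55 ± 0.42 (3 when adjusted over the list alone). That list's median was -0.02, its mean 0.55 and its test upward without passing (adjusted p = 0.231). Of 14 naive pluripotency genes, Tbx3, Klf5 and Klf4 passed, at 1.69 ± 0.34, 1.57 ± 0.33 and 2.47 ± 0.52 (4 when adjusted over the list alone, adjusted p = 0.0802). At D8, KO replicate 1 stood apart for this list, with its median 1.47 above the WT mean against -0.17 and -0.42 in replicates 2 and 3, and for the epiblast list, at 1.25 against -0.09 and -0.15. The largest differences were Serpinb6c, a serine protease inhibitor, at 5.58 ± 0.70, Rhox5, a homeobox gene of the X chromosome, at 3.90 ± 0.59, and Rgs8, a regulator of G-protein signalling, at -7.17 ± 1.31.

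In all 439 genes had a higher and 404 a lower difference. The higher share of 52.1% was 39.6% with DESeq2's size factors, 27% with total counts, where the median shifted by -0.26, and 41.1% once Rn45s was left out. It was 39.9% with the filter of 20 counts in 2 libraries, 46.5% without a filter, 48.4% with a replicate block and 50.3% with DESeq2. Rn45s took at most 0.4787% of counts in any cell library. The count was 61 and 7 without WT D0 replicate 1 and 2, 125 and 296 without WT D8 replicate 1 and 2, 373, 135 and 105 without KO D0 replicate 1, 2 and 3, 3591 without KO D8 replicate 1 and 277 without KO D8 replicate 3.

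Genes of chromosomes 6, 11 and 14 stood higher in KO than in WT on both days. The 501 tested genes of chromosome 14 had a median log2 fold change of 0.467 at D0, with 89.4% above 0, and 0.501 at D8. Chromosome 6 stood at 0.304 and 0.450, and chromosome 11 at 0.197 and 0.239. Chromosome 1 stood higher by less, at 0.098 and 0.077, with 0 and 22 of 1000 random lists as far out. Chromosomes 2, 5 and 7 also had 0 of 1000 as far out at D0, at -0.012, -0.031 and -0.013. At D8 the same held for chromosomes 4 and 7, at -0.074 and -0.08. A place outside the random lists thus does not by itself single out a chromosome. Genes of chromosomes 8 and X stood lower at D0, at -0.150 and -0.186, with 0 of 10000 random lists as far out for each, and at -0.061 and -0.005 at D8. The 2 WT libraries of D0 differed from each other by 0.104 and 0.110 on these chromosomes, a spread that the random lists do not cover. In the KO libraries taken singly, the chromosome 14 median ran from 0.422 to 0.566 over the WT mean, while WT libraries differed from each other by up to 0.103 at D0 and 0.012 at D8. Of the 27 genes higher at D0, 16 (59.3%) lie on chromosomes 6, 11 and 14. These calls rest on single libraries: without KO D0 replicate 1, 2 and 3, the higher genes numbered 11, 1 and 0. Of the 1834 genes higher at D8, 649 (35.4%) lie on these chromosomes, which hold 16.6% of tested genes, and of the 1205 lower genes 80 (6.64%) do. Elsewhere 1185 genes were higher and 1125 lower. When genes of chromosomes 6, 11, 14 and Y were left out, a choice made after the data were seen, 12 genes were called at D0, 2176 at D8 and 684 for the difference between days.

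**Figure D3:**
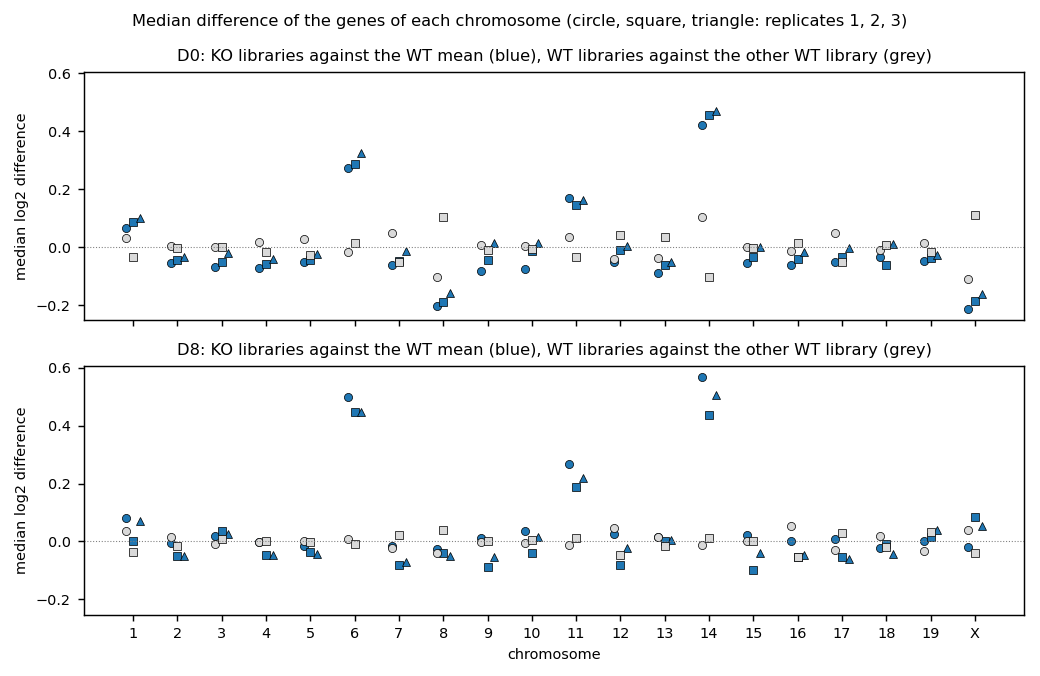
Median log2 difference of the genes of each chromosome (vertical axis) by chromosome (horizontal axis), for KO libraries against the WT mean of the day (blue) and each WT library against the other (grey), D0 above and D8 below. Markers tell replicates apart. Chromosome 14 lies at 0.422 or above in every KO library.

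Genes that separated P from A in the E7.5 embryo were last looked up in the cell line. Of the 29 called higher in P, 26 were tested in cells, and 7 rose and 1 fell in KO against WT at D8 (camera, adjusted p = 0.057). None of the 6 tests of the P and A sets passed, and the 5 genes higher in A, of which 4 were tested, had an adjusted p of 0.484 in the same contrast.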

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

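Of the tests below, those of a single KO library, of the share of neural cells, of shallow A libraries and of uneven visceral endoderm were chosen after the results were seen.

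The P minus A difference changed between E7.0 and E7.5 for 4 genes by a test of the difference itself (0 to 18 when 1 replicate was left out): Fgg (6.13), Slco4c1 (4.94), Mageb16 (4.72) and Amot (3.37, all on the log2 scale). By the same kind of test for lists, the medians of the epiblast (-0.79), immediate early (-1.2), neural ectoderm (-0.72) and visceral endoderm (2.92) lists differed between the stages with the preset correlation, and none with an estimated one.

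The KO minus WT difference changed between D0 and D8 for 843 genes (7 to 3591 when 1 replicate was left out). Among called genes with an average log2 CPM of at least 3, the largest positive differences were Serpinb6c (5.58), Pga5 (5.02), Plbd1 (4.42), Rhox5 (3.90) and 4632428N05Rik (3.83). The largest negative ones were Rgs8 (-7.17), Nacad (-4.28), D430019H16Rik (-4.13), Tubb4a (-3.86) and Gm13889 (-3.78). As lists, neurogenesis (-1.68) and visceral endoderm (2.12) differed between the days, visceral endoderm also with an estimated correlation (adjusted p = 0.0451) and neurogenesis not (adjusted p = 0.639).

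Visceral endoderm genes stood higher in KO (1.45, 1.69 and 2.15 by library) and neurogenesis genes lower at D8, and 6 of 20 visceral endoderm members had too few counts to be tested. The parietal endoderm list stood higher still (2.17, 2.65 and 3.19). It was chosen after the results were seen, so its height against a list fixed in advance is not a test. A single KO library is argued against, since the lowest of the 3 lay 1.45 above the WT mean for the visceral endoderm list. A smaller share of neural cells stays open: the median difference from the WT mean lay at least 1.40 higher for neural ectoderm than for neurogenesis in each KO library, but the same gap was -0.86 and 0.86 in the WT libraries. An effect of the line's chromosome state cannot be told apart from one of the deletion, because all 3 KO D8 libraries carry the chromosome 14 shift. The deletion of Enh9E is the biological difference the design names, and it stays untested against these.

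Visceral endoderm genes stood higher in E7.5 P and AM than in A. Shallow A libraries are argued against, since A replicate 1, the lower in this list, held 16.3 M counts, the highest total of these parts, while A replicate 2 held 9.37 M, the lowest. The A replicates lay 5.07 apart in the list's median log2 CPM, and replicate 1 was the lower in P and AM too. Within a replicate number A lay below P by 6.29 and 3.46 and below AM by 6.90 and 3.68, with the same sign in each. Uneven amounts of visceral endoderm among the dissected pieces may contribute to the size of this difference, and a difference between the regions stays open and untested.

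Genes of chromosomes 6, 11 and 14 stood higher in KO on both days. A single library is argued against by a lowest chromosome 14 median of 0.422 over the 6 KO libraries, and expression level by 0 of 10000 matched random lists lying as far out at D0. A difference in chromosome copy number is a candidate explanation for chromosome 14, where 10 of 10 bins lay above 0.2 at D0, for chromosome 6 with 9 of 10 and for part of chromosome 11 with 5 of 10. The lower medians of chromosomes 8 (-0.150) and X (-0.186) at D0 shrank to -0.061 and -0.005 at D8, and what lies behind them was not tested. DNA copy number was not measured here, and whether the difference arose with the deletion was not tested.

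For KO D8 minus D0, with 9430 genes called, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05, and the highest other split called 0. The real split is the 1 of the 10 that called as many. Each other split mixes D0 and D8 libraries on both sides, which puts the day difference into the spread. Their 0 calls therefore carry no information.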

How the results depend on the processing

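The replicate block within stage, the library sizes without Rn45s and the fit without genes of chromosomes 6, 11, 14 and Y were chosen after the data were seen. DESeq2's size factors, library sizes without Rn45s and the filter of 20 counts in 2 libraries moved none of the 20 counts of genes by over 1.5 times. Of 161 values of named genes that passed, none changed sign under the alternatives checked for them, which leave out the filter of 20 counts in 2 libraries. They kept their side of the threshold in 160 cases with DESeq2's size factors, 159 with DESeq2, 158 without a filter, 147 with total counts and 121 of 160 in fits of the compared groups alone. Without 1 replicate, 610 of 858 such values still passed. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the other groups. Causes were not tested. Fits of the compared groups alone and fits without a library have fewer samples by construction, which does not explain those that called more genes. For D0 KO minus WT, the compared groups alone gave 2033 genes against 40 in the main fit. The chi-square per degree of freedom lay between 3.78 and 7.3 in replicate pairs of D0 and between 12.5 and 63.9 in those of D8. The main fit pools the spread over both days, so its 40 calls do not show that the lines barely differ at D0. For D8 KO minus WT, leaving out KO D8 replicate 1 gave 5463 against 3039. Alternatives planned for values other than counts do not apply. Of simulated 2-fold changes, 0 to 7.46% were recovered in embryo comparisons and 26.9% in WT D8 minus D0, which also has 2 libraries per group.

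DESeq2 called 2066 genes for E6.5 ExE, 14 for E7.0 P minus A, 238 for E7.5 P minus A, 581 for AM minus A, 123 for AM minus P, 21 for the change in P minus A, 43 for E7.0 minus E6.5, 583 for A over time, 115 for P over time, 439 for ExE over time, 444 for D0 KO minus WT and 1780 for the KO difference between days. It gave 576 genes lower in ExE at all 3 stages and 5 shared P minus A genes.

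Fits of only the compared groups called 3643 for E6.5 ExE, 1009 for E7.0 ExE, 0 for E7.0 P minus A, 21 for E7.5 P minus A, 3 for AM minus A, 0 for AM minus P, 1 for the change in P minus A, 0 for A over time, 19 for P over time, 355 for ExE over time, 2033 for D0 KO minus WT and 705 for D8 KO minus WT.

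With no low-count filter edgeR called 71 for E7.0 P minus A, 391 for E7.5 P minus A, 653 for AM minus A, 189 for AM minus P, 121 for the change in P minus A, 153 for E7.0 minus E6.5, 632 for A over time, 219 for P over time, 485 for ExE over time and 70 for D0 KO minus WT, and 24 genes were shared P minus A.

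With total counts only, 10 genes were called for E7.5 P minus A, 0 for the change in P minus A, 161 for A over time, 66 for ExE over time and 25 for D0 KO minus WT, and 212 were lower in ExE at all 3 stages. Without genes of chromosomes 6, 11, 14 and Y, 12 were called for D0 KO minus WT. Of the list tests, 137 passed with camera's preset correlation, 45 with the estimated correlation and 101 with fry. Of the 68 lists described that passed, 31 did not with the estimated correlation and 16 did not with fry.

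Replicate numbers were checked as pairs. In embryos, deviations from group means of same-numbered libraries of a stage correlated at 0.038 to 0.555 over 20 pairs, with the highest between E7.5 AM and P. With 2 libraries per embryo group, the deviations within a group mirror each other. Replicates 1 and 2 thus give the same value, and each value is counted 2 times among the 20. In cells the range was -0.042 to 0.037 over 5 pairs of a line across days, and KO and WT libraries of a day correlated at 0.177 and 0.099 at D0 and at 0.103 and 0.167 at D8. The labels do not say what a number marks. Y-linked genes split by number at E6.5 and E7.5, which shared embryos would give and shared sex alone would give too, and the fit without a block was kept as planned. With the replicate block, 78 genes were called for E7.5 P minus A, 370 for AM minus A, 28 for AM minus P, 230 for A over time, 31 for P over time and 6 for D0 KO minus WT (2 higher and 4 lower, against 27 and 13 without the block), and 545 were higher in ExE at all 3 stages. With the replicate block within stage the counts were 3 for E7.0 P minus A, 129 for E7.5 P minus A, 437 for AM minus A, 35 for AM minus P, 5 for E7.0 minus E6.5, 371 for A over time and 127 for P over time, with 565 higher in ExE at all 3 stages and 1 shared P minus A gene.

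Leaving out 1 replicate at a time gave 355 to 603 genes for E6.5 ExE, 1245 to 4555 for E7.0 ExE and 661 to 2921 for E7.5 ExE. The ranges were 0 to 0 for E7.0 P minus A, 0 to 76 for E7.5 P minus A, 36 to 205 for AM minus A, 0 to 10 for AM minus P and 0 to 18 for the change in P minus A. Over time they were 0 to 1 for E7.0 minus E6.5, 14 to 163 for A, 0 to 9 for P and 16 to 97 for ExE. In cells they were 6564 to 6952 for WT D8 minus D0, 8177 to 9905 for KO, 3 to 15 for D0 KO minus WT, 777 to 5463 for D8 KO minus WT and 7 to 3591 for the KO difference between days. Genes higher in ExE at all stages numbered 78 to 344 and lower 100 to 346, and shared P minus A genes 0.

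Among named genes that did not pass, 3 changed sign. Cdx2 in E7.5 ExE was -0.11 with total counts, and -0.25, -0.21, -1 and -0.12 without A, AM, ExE and P replicate 1, and at most 0.88, without A replicate 2. Dppa3 in WT D8 minus D0 was 0 without WT D8 replicate 1 and -1.92 without replicate 2, and Sox2 in D8 KO minus WT was 0.11 without WT D8 replicate 2 and -0.63 without replicate 1.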

Other observations

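The parietal endoderm list and its test were chosen after the results were seen, so its p-values are descriptive and lend no independent support.

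Parietal endoderm, the layer that lays down the basement membrane around the rodent embryo, shares some genes with visceral endoderm: 4 of the 20 genes of this list are also in the visceral endoderm list. In KO cells at D8, 19 of the 20 were higher than in WT, also when adjusted over the list alone, with a median log2 fold change of 2.66 (camera, adjusted p = 8.57e-25, and adjusted p = 0.0574 with an estimated correlation). Members that rose include the laminin chains Lama1 (2.71), Lamb1 (2.91) and Lamc1 (2.56), the collagen IV chains Col4a1 (2.51) and Col4a2 (2.54), and Nid1 (3.23). The transcription factors Sox17 (3.04) and Sox7 (2.60) rose as well, and Cubn did not pass, at 1.10. The KO D8 libraries lay 2.17, 2.65 and 3.19 above the WT mean in the list's median, with the WT libraries at -0.31 and 0.31. At D0 none of the 20 passed over all genes or when adjusted over the list alone (adjusted p = 0.94). For the difference between days 12 passed, and all 20 when adjusted over the list alone (adjusted p = 0.187 with an estimated correlation).

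Y-linked transcripts divided the embryo libraries by replicate at some stages. Ddx3y stood at 76.7 and 82.0 CPM in E6.5 Epi and ExE replicate 1, and at 0 and 0.141 in replicate 2. At E7.5 it stood at 59.4, 67.4, 57.0 and 60.8 CPM in replicate 1 of A, AM, ExE and P, and at 0 in replicate 2 of each. At E7.0 all 6 libraries held it, at 54.5 to 98.0 CPM. Xist, the transcript of the inactive X chromosome, stood at 196 and 200 CPM in E6.5 Epi and ExE replicate 2 and at 6.39 and 14.9 in replicate 1. At E7.5 it stood at 64.2, 78.4, 27.2 and 61.4 CPM in replicate 2 of A, AM, ExE and P, and at 1.16 to 7.87 in replicate 1. At E7.0 it stood at 34.4 CPM in ExE replicate 2, which also held Ddx3y at 65.4. The other E7.0 libraries had Xist at 4.03 to 11.3 CPM.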
